A study of Caenorhabditis elegans with 3 samples.

How the data were processed

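RNA of *Caenorhabditis elegans* late L4 hermaphrodites was measured on 3 two-colour arrays of 20000 features each. Each array carried RNA of 1 late L4 preparation (prep 1, 2 or 3) in channel 2 and wild-type mixed reference RNA in channel 1, per the labels, so the 3 arrays formed 1 group and 0 of them were dye-swapped. A dye effect specific to a gene could therefore not be separated from a difference between the RNAs. The labels do not say that the preps came from separate cultures, so the p-values measure the spread between these preps, which may be technical. The sample labels carry a code taken here as time point 5, the same on all 3 arrays. Each array title ends in a different date, so an effect of that date cannot be told apart from one of the prep. Beyond this, the labels give no purpose for the series other than the comparison itself.

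The authors deposited 1 log2 value per feature and array. Raising 2 to each deposited value gave a multiple of 0.001, within 0.05 of a step, for 100% of the values on every array, so the values were base-2 logarithms of ratios rounded to 3 decimals; the same check on the inverse ratios held for 10.4 to 11.0% of the values. The dyes, background correction, normalization, scale and probe type are not given in the sources used here. The direction, late L4 over reference, is likely and not certain: it rests on the order in which the sample descriptions name the RNAs and on the channel contents. Spot intensities were not analysed here, so signal over background is unknown and dim spots could not be filtered. Values were measured for 19903, 19840 and 19825 features on preps 1, 2 and 3, with medians of 0.01, -0.10 and -0.06 and SDs of 0.967, 0.854 and 0.893 log2 units. They were used as deposited.

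Of the 20000 features, 15655 had 1 gene symbol in the platform annotation, 198 had several and 4147 had none listed. Symbols were updated by Entrez ID, which matched 15569 features, with a RefSeq gene table for assembly WBcel235. No genome build is named for the arrays, so no coordinates are given and only chromosome names were used. The 19736 features measured on all 3 arrays were averaged per gene within each array, and features without a single gene stayed as rows of their own. This left 19292 rows, 15112 named genes and 4180 unnamed features, all called genes below. Of the 425 genes with several features, 0 had features called in opposite directions and 13 had features more than 1 log2 unit apart.

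The mean log2 ratio of the 3 arrays was tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 12.8 degrees of freedom at an SD of 0.438 log2 units, so most of the information on the spread came from other genes. The reference had no replicate, and the test leaves out its own spread. The number of arrays limits the precision. Fold changes are 2 to the power of the mean log2 ratio, and errors are SDs over the arrays.

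Before the data were examined, 20 gene lists were fixed from textbook knowledge, as were the comparison of X-linked with autosomal genes and most alternative settings. Each list was tested two-sided against all other genes with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation, which works with the 2 residual degrees of freedom here, and fry, which asks whether the genes of a list move on balance one way without comparing them to other genes, were alternatives. The rule for named genes, also fixed then, took the 6 highest and 6 lowest mean log2 ratios among called genes with the same sign on all 3 arrays, and from each list the 2 called members with the largest absolute mean, filled up by lowest p. Genes named outside it were chosen after their values were seen and are marked so.

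The other alternatives were median centring of each array, centring with scaling between arrays, values on at least 2 arrays, robust eBayes, variance without moderation, features not averaged per gene, stricter thresholds and leaving out each prep. A fit on named genes only was added after seeing the data. The procedure was tested on simulated data for 19292 genes, of which 200 were changed: 39% of the 2-fold and 99% of the 4-fold changes were recovered, 8 of 19052 unchanged genes were called, the shifted list was called and 0 of 19 unshifted lists were. An earlier version of the simulation drew its noise from each gene's raw SD over the 3 arrays and fell short of the recovery set for 4-fold changes; the figures given come from its replacement, which draws the spread from limma's fitted prior and so takes limma's variance model as true. Simulated genes were drawn independently of each other, so the simulation cannot show how often lists of correlated genes are called falsely. In the arrays, the correlation estimated for the major sperm protein list was 0.37. The simulation also changed far fewer genes than were called in the data, so its recovery need not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.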

Results

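Transcript levels of late L4 hermaphrodites, animals in the last larval stage before the adult molt, were compared with a wild-type mixed reference on 3 arrays, 1 for each of 3 RNA preps. The log2 ratios had Pearson correlations across 19292 genes of 0.70 between preps 1 and 2, 0.73 between preps 1 and 3 and 0.69 between preps 2 and 3, with Spearman coefficients of 0.58, 0.59 and 0.55; genes are not independent replicates. The single comparison asked which transcripts were more or less abundant in late L4 RNA than in the reference. Positive values stand for higher levels in late L4 throughout, a direction that is likely from the sample descriptions but is not stated with the values.

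In late L4, 2322 of 19292 genes were higher and 2092 were lower than in the reference (limma, adjusted p under 0.05). Of these, 1660 of the higher and 1168 of the lower genes differed at least 2-fold, and 153 and 44 at least 8-fold. The sign was the same on all 3 arrays for 2293 of the higher and 2066 of the lower genes. The highest mean belonged to *irg-5* (F35E12.5), an infection response gene, at 56.0-fold (log2 ratio 5.81 ± 0.45, SD, n = 3; adjusted p = 1.07e-08). The next 5 were all cuticle collagen genes, *col-38* (F54C9.4), *col-120* (Y11D7A.11), *col-60* (F22D6.10), *col-175* (C35B8.1) and *col-161* (C50B6.4), with means from 29.7-fold down to 23.6-fold higher. At the other end, *acs-2* (F28F8.2), an acyl-CoA synthetase of fatty acid oxidation, was 33.9-fold lower (log2 ratio -5.08 ± 0.75, SD, n = 3; adjusted p = 3.30e-08). The collagen gene *col-36* (C27H5.5) was 33.4-fold lower (20.2-fold without prep 1), the small heat shock protein gene *hsp-12.6* (F38E11.2) 32.1-fold, the collagen gene *col-158* (D2023.7) 24.6-fold and *ule-1* (W03F11.1) 18.4-fold, and *cup-16* (C34C6.7) had a mean log2 ratio of -4.65 ± 0.29. The count of lower genes was 1340 without prep 1 and 1357 without prep 3, and 1289 and 1291 of the 2092 were also lower there. With each gene's own variance in place of the moderated one, limma called 0 genes, and 1874 higher and 2340 lower genes had an unadjusted p under 0.05.

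**Figure D1:**
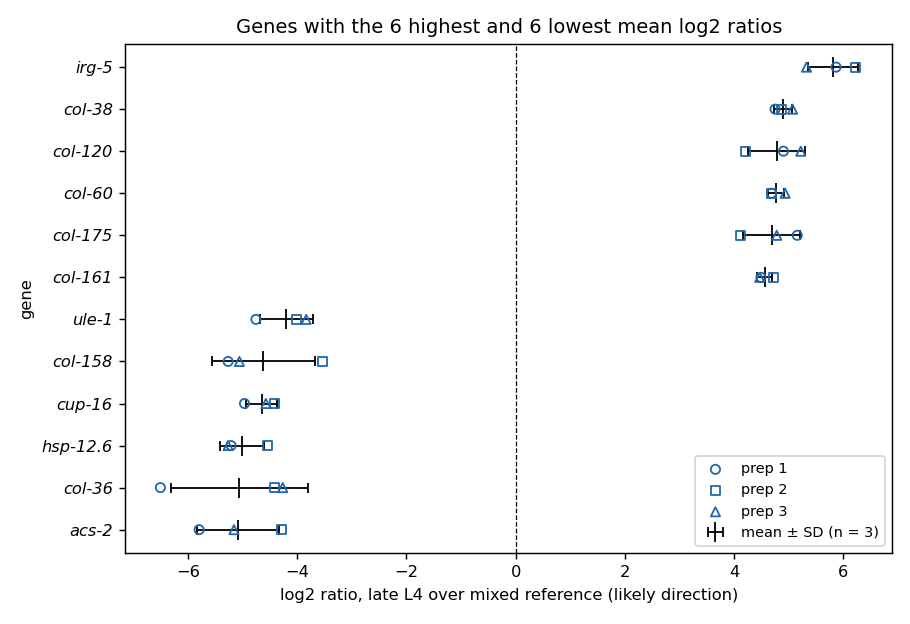
Log2 ratio, late L4 over mixed reference (likely direction), of the 12 genes with the 6 highest and 6 lowest means. Symbols are the 3 preps and bars the mean ± SD (n = 3). The means run from 5.81 for *irg-5* to -5.08 for *acs-2*. All 3 values of each gene lie on the same side of 0 because the selection required it.

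Of 30 major sperm protein genes, which encode the cytoskeletal protein that moves nematode sperm, 29 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median log2 ratio of 2.98 (camera, adjusted p = 3.71e-33; adjusted p = 0.18 with an estimated correlation). *msp-56* was 18.3-fold higher (log2 ratio 4.19 ± 0.51, SD, n = 3) and *msp-33* 15.3-fold (3.93 ± 0.33). The gene that did not pass, named after its values were seen, was *msp-38* at 0.02 ± 0.20, a mean that became -0.08 without prep 1. Of 34 other genes of sperm formation and function, 26 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.64 (camera, adjusted p = 1.51e-19; adjusted p = 0.18 with an estimated correlation), among them *smz-2* at 13.7-fold (3.78 ± 0.05) and *ssq-1* at 12.2-fold (3.60 ± 0.69). Members of the msp, ssp and ssq families have near-identical copies, and single members are uncertain because the probe type is not given. For the same reason 1 signal may be counted under several genes, in the counts and in the camera p-values of both lists.

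Among 30 germ line RNA regulators and P granule genes, 9 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.43 (camera, adjusted p = 0.000367; adjusted p = 0.41 with an estimated correlation and 0.053 with fry). The Vasa-related helicase genes *glh-1* and *glh-2* were 4.46-fold and 3.82-fold higher (log2 ratios 2.16 ± 0.34 and 1.93 ± 0.34, SD, n = 3). Of 27 genes of meiotic chromosome pairing and recombination, 1 was higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.01 (camera, adjusted p = 0.72). *syp-1*, a component of the synaptonemal complex, was 2.27-fold higher (1.18 ± 0.35, adjusted p = 0.00232). *him-5*, needed for crossovers on the X, was 2.01-fold lower (SD 0.32 log2 units, n = 3; limma, adjusted p = 0.00710), and its call was lost without prep 2 (adjusted p = 0.071).

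Of 35 oocyte, eggshell and maternal genes, 12 were lower, 0 higher and 23 did not pass (15 lower and 0 higher adjusted over the list alone), with a median of -0.45 (camera, adjusted p = 3.77e-05; adjusted p = 0.51 with an estimated correlation and 0.15 with fry). The median was -0.30 on prep 1, -0.30 on prep 2 and -0.88 on prep 3, and -0.42 without prep 3. The caveolin gene *cav-1* was 6.46-fold lower (log2 ratio -2.69 ± 1.15, SD, n = 3; 4.09-fold without prep 1) and *cpg-3*, an eggshell proteoglycan gene, 4.02-fold (-2.01 ± 0.41). Of the 3 measured vitellogenin genes, which encode yolk proteins, 1 was lower and 0 higher (1 and 0 adjusted over the list alone), and the list's median was -0.13 (camera, adjusted p = 0.65). *vit-2* was 2.66-fold lower (log2 ratio -1.41 ± 1.63, adjusted p = 0.023), which rested on prep 3: without it the mean was -0.48 (adjusted p = 0.34). The call was also lost under median centring, scaling and robust eBayes (adjusted p = 0.064, 0.094 and 0.26). *vit-6* had a mean of 0.20 ± 0.39 and did not pass. Of 51 genes first transcribed in the embryo, 5 were lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -0.29 (camera, adjusted p = 0.020; adjusted p = 0.31 with an estimated correlation). The count of lower genes was no excess, since 10.8% of all genes tested were lower. Without prep 2 this list missed the threshold (median -0.25, adjusted p = 0.21). *sdz-24* was 2.83-fold lower (-1.50 ± 0.59) and *sdz-37* 2.04-fold (-1.03 ± 0.26); the others, named after their values were seen, were *tbx-9* (-0.80 ± 0.57), *med-1* (-0.78 ± 0.11) and *nob-1* (-0.72 ± 0.13), and leaving out any 1 prep ended the calls of *med-1* (adjusted p from 0.060 to 0.12) and *nob-1* (from 0.082 to 0.18). *tbx-9* lost its call without prep 2 (adjusted p = 0.066) and without prep 3 (adjusted p = 0.32), and both *tbx-9* and *nob-1* lost theirs under median centring (adjusted p = 0.066 and 0.056).

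Cuticle collagen genes included strongly higher and strongly lower members. Of 152 measured, 82 were higher and 24 lower (87 and 26 adjusted over the list alone), 78 and 19 of them at least 2-fold, and the median was 1.13 (camera, adjusted p = 3.34e-13; adjusted p = 0.18 with an estimated correlation). *col-38* was 29.7-fold higher (log2 ratio 4.89 ± 0.16, SD, n = 3) and *col-36* 33.4-fold lower (-5.06 ± 1.25, and -4.34 without prep 1). Of 62 molting genes, 10 were higher and 6 lower (10 and 6 adjusted over the list alone), with a median of 0.17 (camera, adjusted p = 0.47). The molting median was -0.09 on prep 1, 0.18 on prep 2 and 0.22 on prep 3, and 0.053 without prep 3. Some single members differed far more between preps than this median. Named after its values were seen, *mlt-10* had log2 ratios of -1.20, 0.66 and 2.26 on preps 1, 2 and 3. The ratios of *grd-8*, chosen likewise, were 1.79, -0.40 and -0.61, and neither gene passed. *grd-6*, of the Hedgehog-related groundhog family, was 5.78-fold higher (2.53 ± 0.89) and *nas-36*, an astacin protease gene, 4.94-fold (2.30 ± 0.28). Of 13 abu family genes, named for their activation when the unfolded protein response is blocked, 11 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 3.05 (camera, adjusted p = 1.51e-12; adjusted p = 0.18 with an estimated correlation). *abu-15* was 11.3-fold higher (3.49 ± 0.93) and *abu-6* 10.4-fold (3.38 ± 1.19), or 6.51-fold without prep 1; *abu-13* (0.53 ± 0.60) and *abu-14* (0.24 ± 0.26), named after their values were seen, did not pass. Single collagen and abu genes, and the counts and camera p-values of both lists, are uncertain for the same reason as the sperm families.

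**Figure D2:**
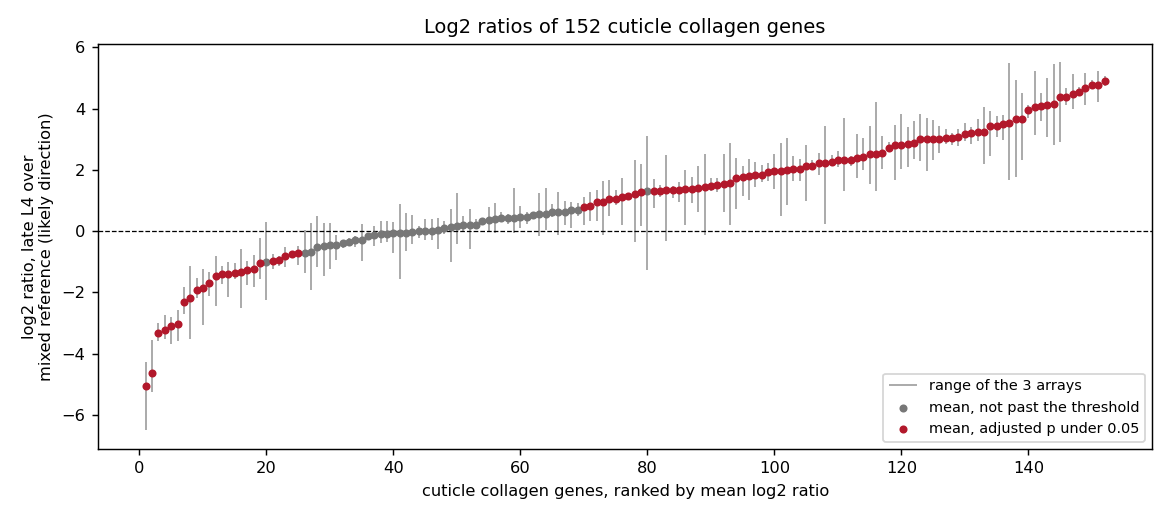
Mean log2 ratio, late L4 over mixed reference (likely direction), of 152 cuticle collagen genes in rank order. Points are means over 3 arrays, red where the adjusted p was under 0.05, and lines span the lowest to the highest array; 82 genes were higher and 24 lower.

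Of 31 body wall muscle genes, 14 were higher, 0 lower and 17 did not pass (21 higher and 0 lower adjusted over the list alone), with a median of 0.64 (camera, adjusted p = 3.63e-08; adjusted p = 0.18 with an estimated correlation). *tnt-2*, a troponin T gene, was 4.11-fold higher (log2 ratio 2.04 ± 0.51, SD, n = 3) and *unc-52*, which encodes perlecan, 4.10-fold (2.04 ± 0.36). Of 55 neuronal genes, 29 were lower, 1 was higher and 25 did not pass (29 lower and 1 higher adjusted over the list alone), 24 of the lower ones at least 2-fold, with a median of -0.79 (camera, adjusted p = 5.70e-10; adjusted p = 0.28 with an estimated correlation). The FMRFamide-like neuropeptide genes *flp-1* and *flp-4* were 6.36-fold and 4.30-fold lower (log2 ratios -2.67 ± 0.38 and -2.11 ± 0.48). The list takes in all measured flp genes. Its other members were not tested apart from them, so the median does not stand for neuronal genes other than neuropeptide genes. The higher gene, named after its value was seen, was the amine synthesis gene *bas-1* (0.75 ± 0.13), whose call was lost without any 1 prep (adjusted p = 0.068, 0.15 and 0.14 without preps 1, 2 and 3).

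Of 50 intestinal genes, 14 were higher and 12 lower (16 and 12 adjusted over the list alone; camera, adjusted p = 0.65). The median was -0.05, while the mean was 0.10 and camera's direction upward, and the median became 0.036 under centring with scaling. The list takes in all measured lys and spp genes beside other intestinal genes. These parts were not tested separately, so a median near 0 does not show that none of them shifted. *cpr-5*, a cathepsin B-like protease gene, was 9.57-fold higher (log2 ratio 3.26 ± 0.53, SD, n = 3) and the metallothionein gene *mtl-1* 8.68-fold lower (-3.12 ± 0.44). Of 13 pharyngeal genes, 3 were higher and 3 lower (4 and 4 adjusted over the list alone), with a median of 0.07 (camera, adjusted p = 0.65). *phat-4*, a pharyngeal gland gene, was 7.31-fold higher (2.87 ± 0.76) and its relative *phat-5* 3.34-fold lower (-1.74 ± 1.30), or 2.19-fold without prep 1 and 5.35-fold without prep 2. The others, named after their values were seen, were *phat-2* (1.19 ± 0.27) and the troponin T gene *tnt-4* (1.06 ± 0.16) among the higher genes, and the troponin C gene *tnc-2* (-1.70 ± 0.65) and *phat-1* (-0.98 ± 0.46) among the lower genes. *phat-1* lost its call without prep 1 (adjusted p = 0.12).

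Of 54 ribosomal protein genes, 13 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.51 (camera, adjusted p = 3.64e-06; adjusted p = 0.18 with an estimated correlation). *rpl-4* was 2.40-fold higher (log2 ratio 1.26 ± 0.68, SD, n = 3) and *rps-7* 2.50-fold (1.32 ± 1.13), a call lost without prep 2 (mean 0.67, adjusted p = 0.18). Of 44 genes of DNA replication and cell division, 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.03 (camera, adjusted p = 0.65). The kinetochore gene *hcp-1* was 2.27-fold higher (1.18 ± 0.52) and *klp-7*, a microtubule-depolymerising kinesin gene, 2.24-fold (1.17 ± 0.55), which was lost without prep 2 (adjusted p = 0.062). Named after their values were seen, *hcp-2* was also higher (0.98 ± 0.39), a call lost without prep 3 (adjusted p = 0.095), and the ribonucleotide reductase gene *rnr-2* lower (-1.06 ± 0.21). Of 62 core and linker histone genes, 4 were lower and 1 higher (3 and 1 adjusted over the list alone), with a median of -0.08 (camera, adjusted p = 0.65). *hil-3* and *his-24*, both linker histone genes, were 4.55-fold and 3.47-fold lower (-2.18 ± 0.39 and -1.79 ± 0.57); the others, named after their values were seen, were the linker histone gene *hil-7* (-1.51 ± 0.23), *his-37* (-0.68 ± 0.09) and the higher *his-70* (1.66 ± 0.34). *his-37* lost its call without any 1 prep (adjusted p from 0.13 to 0.17) and under median centring (adjusted p = 0.070), and single core histone genes are uncertain because of their near-identical copies.

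Of 8 heat shock genes, 3 were lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -0.40 (camera, adjusted p = 0.00806; adjusted p = 0.43 with an estimated correlation, 0.10 with fry and 0.13 without moderation of the variance). The small heat shock protein genes *hsp-12.6* and *hsp-12.3* were 32.1-fold and 6.75-fold lower (log2 ratios -5.01 ± 0.40 and -2.75 ± 0.55, SD, n = 3). *hsp-70* (-0.93 ± 0.59), named after its values were seen, lost its call without prep 1 (adjusted p = 0.19). The list's median was -1.53 on prep 1, 0.17 on prep 2 and -0.29 on prep 3, and -0.06 over the other preps without prep 1 or -0.88 without prep 2. Of 14 genes of the vulva and its morphogenesis, 1 was lower and 0 higher (1 and 0 adjusted over the list alone), with a median of -0.23 (camera, adjusted p = 0.13). This gene was *egl-26* (-0.90 ± 0.45, adjusted p = 0.017), whose call was lost without prep 1 (adjusted p = 0.14) and without prep 2 (adjusted p = 0.056). *sqv-7*, a nucleotide sugar transporter gene, had a mean of -0.76 ± 0.60 (adjusted p = 0.052) and passed without prep 3 (adjusted p = 0.036) and with robust eBayes (adjusted p = 0.045). Of 10 male-specific genes, limma called 0 (0 adjusted over the list alone), with a median of -0.04 that turned to 0.0086 under median centring (camera, adjusted p = 0.72). *try-5*, a seminal fluid protease gene, had a mean of -0.41 ± 0.28 and *cwp-4* one of -0.38 ± 0.10.

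**Figure D3:**
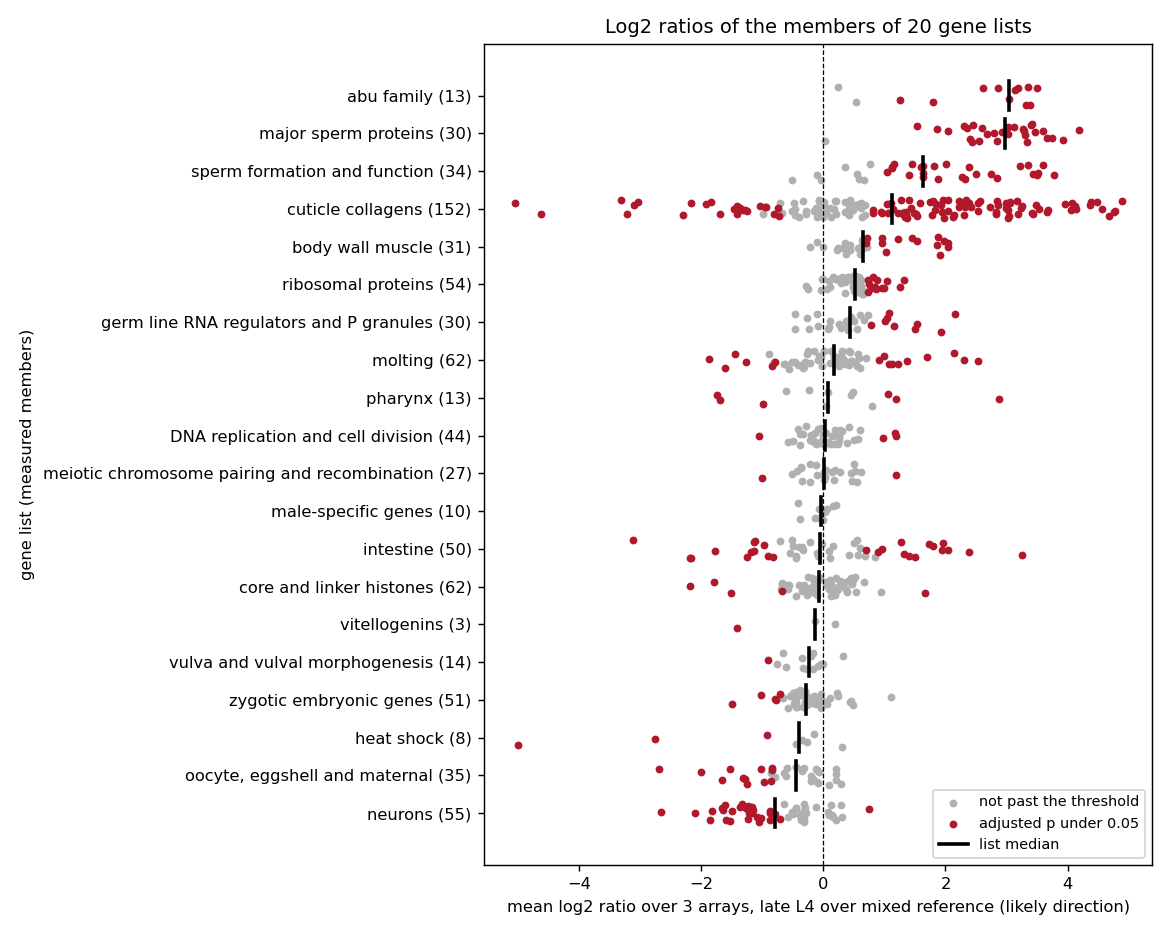
Mean log2 ratio, late L4 over mixed reference (likely direction), of each measured member of 20 gene lists, with the number of members in brackets. Points are genes, red where the adjusted p was under 0.05, and bars are list medians, which run from 3.05 for the abu family to -0.79 for neuronal genes; the medians of the intestinal and male-specific lists change sign under rescaling.

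The 2275 X-linked genes had a median log2 ratio of -0.14 and the 12837 autosomal genes one of -0.02, a difference of -0.12 (camera, p = 0.016; p = 0.010 with an estimated correlation). On the X, 171 genes (7.52%) were higher and 327 (14.4%) lower, against 1748 (13.6%) and 1489 (11.6%) on the autosomes. Among separate tests of all 6 chromosomes, the adjusted p of the X was 0.095. Chromosome V had a median of -0.11 (camera in limma, adjusted p = 0.17).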

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

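No paired analysis was possible because the arrays form only 1 group. Signal over background is unknown, so its limits could not be tested. Apart from the fit on named genes only, which was chosen after seeing the data, the alternatives were planned. The cause of the differences was not tested except where stated.

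Lower genes numbered 1168 at 2-fold or more and 1217 at an adjusted p under 0.01, both stricter thresholds. Leaving out 1 prep gave 1340 to 1768 lower and 1793 to 2047 higher genes, with fewer arrays fitted. Without moderation both counts were 0, since 2 degrees of freedom per gene remained. Median centring gave 2350 higher and 1703 lower genes, a higher share of 58.0% against 52.6%.

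With an estimated correlation, which also leaves 2 degrees of freedom, the lists with these medians missed the threshold: abu 3.05, major sperm proteins 2.98, sperm function 1.64, collagens 1.13, muscle 0.64, ribosomal proteins 0.51, germ line RNA regulators 0.43, zygotic genes -0.29, heat shock -0.40, oocyte -0.45 and neurons -0.79. Germ line RNA regulators, oocyte and heat shock genes also missed it with fry, and heat shock genes without moderation (-0.40).

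Medians near 0 of lists that never passed changed sign. Median centring gave 0.0086 for male-specific genes; with scaling they had 0.0027 and intestinal genes 0.036. Leaving out 1 prep gave ranges of -0.16 to 0.087 for male-specific, -0.20 to 0.13 for intestinal, -0.065 to 0.11 for meiotic, -0.032 to 0.19 for pharyngeal, -0.13 to 0.056 for histone, -0.047 to 0.13 for replication and -0.29 to 0.052 for vitellogenin genes. Molting genes ranged from 0.053 to 0.20 and kept their sign. Among single genes, *vit-6* ranged from -0.025 to 0.32 and *msp-38* from -0.084 to 0.11, both below 0 without prep 1. Zygotic genes ranged from -0.34 to -0.25 and missed the threshold without prep 2.

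The X difference ranged from -0.15 to -0.11 with p from 0.014 to 0.039 over 11 settings, the reported one included. The 92 named genes counted next leave out *mlt-10* and *grd-8*. Of these 92, 86 kept direction and side of the threshold under median centring and 89 under robust eBayes. The number was 77 without prep 1, 82 without prep 2, 77 without prep 3 and 8 without moderation.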

Other observations

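Families sharing a name stem were compared after the data had been seen. Of 134 families, 22 had a camera adjusted p under 0.05, and 0 did with an estimated correlation (adjusted p = 0.68 or more for every family). The 7 of lowest camera p are described, and the other 15 are not. The neuropeptide-like nlp family had 33 of 53 genes lower and 2 higher (median log2 ratio -1.12; camera, adjusted p = 1.27e-09; adjusted p = 0.68 with an estimated correlation), with *nlp-8* 5.23-fold lower and *nlp-25* and *nlp-4* 3.42-fold and 2.06-fold higher. The spe family, part of which is in the sperm list, had 14 of 24 genes higher and 0 lower (median 0.98; camera 2.78e-06, estimated correlation 0.68, both adjusted p). Of 42 nssp genes, 11 were lower and 0 higher (median -0.43; 0.000271 and 0.68), and of 24 pals genes 10 were lower and 0 higher (median -0.55; 0.000271 and 0.68), with *pals-39* 11.2-fold lower. Of 46 transthyretin-related ttr genes, 19 were lower and 3, *ttr-9*, *ttr-12* and *ttr-14*, higher (median -0.59; 0.000523 and 0.68). Of 11 acyl-CoA dehydrogenase acdh genes, 6 were higher and 0 lower (median 0.76; 0.00103 and 0.68), with *acdh-1* at 10.2-fold. Of 63 UDP-glucuronosyltransferase ugt genes, 20 were higher, *ugt-22* at 14.8-fold, and 5, *ugt-15*, *ugt-18*, *ugt-24*, *ugt-54* and *ugt-55*, lower (median 0.42; 0.00405 and 0.68). Genes named here were chosen after their values were seen. *nlp-4* lost its call without prep 3 (adjusted p = 0.26), and *ttr-12*, *ugt-15*, *ugt-54* and *ugt-55* lost theirs without prep 1 (adjusted p = 0.15, 0.14, 0.14 and 0.063) and without prep 3 (adjusted p = 0.15, 0.30, 0.099 and 0.075). *ugt-15* had log2 ratios of -1.80, 0.39 and -2.13 on preps 1, 2 and 3 and a mean of -1.18, or -1.96 without prep 2, and its call was also lost under median centring (adjusted p = 0.085), centring with scaling (0.11) and robust eBayes (0.15).

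Tests chosen only after the result was seen were those of dilution by the germ line, of a single prep, of paralogs, of germ line size, of males and of sign patterns; the others were written before. All concern hypotheses found in these same data, and the composition of the reference is unknown beyond its label. Changing the sign of single arrays gives 4 patterns, too few for a share under 0.05; 1 of the 4, the real one, gave 4414 calls, and the highest other gave 0.

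Of 55 neuronal genes, 29 were lower in late L4. Features near background could pull neuronal genes to the level of other sparsely expressed genes. The neuronal median lay -0.71 from that of 1052 chemoreceptor genes, of which 24 were lower and 10 higher. Without intensities neither set is known to lie near background, so the comparison cannot decide that explanation. X linkage is argued against by the median of -0.72 of the 39 autosomal neuronal genes, and dilution of all somatic RNA by the muscle median of 0.64. A smaller share of neuronal RNA in late L4 may be involved and stays open: a second neuronal list had 10 of 47 genes lower and 0 higher and a median of -0.29 (camera, p = 0.000989; p = 0.17 with an estimated correlation), just short of the -0.3 set beforehand. The 55 genes include the flp neuropeptide genes, and the nlp neuropeptide family had a median of -1.12, further below 0 than the second list. Whether neuropeptide genes fell more than other neuronal genes was not tested. Gene-specific dye effects could not be tested.

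The genes *acs-2*, *hsp-12.6*, *hsp-12.3* and *mtl-1* were picked after their low values were seen and stand for no tested group: 5 of the 8 heat shock genes did not pass, and *mtl-2*, the other metallothionein gene measured, also named after its values were seen, had a mean of 0.67 ± 0.40 and was not called. A single prep is not behind their low means, although they were picked for those: the least lowered of the 4 genes' values on any array was -2.24. RNA of starved or dauer animals in the reference is a candidate explanation: of 8 genes induced by the transcription factor DAF-16, *scl-1*, *icl-1* and *nnt-1*, named after their values were seen, were lower, 0 were higher and 5 did not pass (median -0.35; camera, p = 0.029, adjusted p = 0.049; p = 0.24 with an estimated correlation). The 5 that did not pass had mean log2 ratios from -0.40 to 0.15 (limma, adjusted p from 0.35 to 0.91), so this candidate rests on 3 of the 8 genes. A list of 11 fasting-response genes did not pass (median -0.30; camera in limma, adjusted p = 0.16 over 5 lists), with *fil-1*, *fil-2*, *hacd-1* and *lipl-2* lower and *lipl-5* and *ech-1.1* higher, all named after their values were seen, of which *lipl-2* lost its call without any 1 prep (adjusted p = 0.39, 0.055 and 0.050 without preps 1, 2 and 3) and *ech-1.1* without prep 1 or 3 (adjusted p = 0.17 and 0.18). A lower expression of these genes in late L4 itself could give the same ratios as more of their RNA in the reference.

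Of 34 sperm genes, 26 were higher in late L4. A larger germ line as the whole cause would need other germ line genes to be raised alike. The meiotic list argues against that (median 0.01, quartiles -0.22 and 0.36, against a lower quartile of 1.06 for sperm genes). The oocyte median of -0.45 (-0.42 without prep 3, which stood lowest) cannot decide it, since oocyte genes may follow the stage of gamete formation and not germ line size. Germ line RNA regulators, with 9 of 30 higher, 0 lower and a median of 0.43, leave a larger germ line open as a part of the cause. Hybridisation between near-identical paralogs is not excluded: sperm genes outside the large families had a median of 1.12 with 9 of 15 higher and 0 lower (camera, p = 7.49e-06; p = 0.056 with an estimated correlation), including *spe-11* and *spe-26*, its highest, chosen after their values were seen, but the test had asked for at least 10 higher. Males among the animals cannot be told apart from hermaphrodites by the male-specific median of -0.041, since no intensities show those genes to be measurable. Spermatogenesis in the L4 stage stays open as an untested biological explanation.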
